A study of Mus musculus with 4 samples.

How the data were processed

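RNA from 4 mouse adenoma colonoid lines was sequenced, one library per line. Colonoids are epithelial structures grown in culture from colon tissue, here from animals with the Apcmin allele. RNA was isolated with an RNeasy column kit and the libraries were made by a commercial service, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0, HISAT2 2.1.0, StringTie 2.1.1, R 3.5.2 and DESeq2 1.32.0, and the mouse genome build mm10. The annotation used for counting, the strand setting and the filters on reads are not given in the sources used here.

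The authors deposited one table of 16857 genes by 4 libraries, in which each value is on a log2 scale and the lowest value of every library is 6.508. A shared floor of this kind is what a variance-stabilizing transformation with a parametric dispersion trend gives to a count of 0. The transformation was inverted with the floor as its only constant, which returned normalized counts, and one scale factor per library then turned 100% of the values into whole numbers within a tolerance of 0.001. On 16000 simulated genes the same steps returned 100% of the values. The whole numbers are called counts here, but StringTie reports estimated coverage, so they can be rounded estimates and not reads counted one by one. Their totals were 17152994 and 17901744 for G0 replicates 1 and 2, and 16545429 and 17156331 for G2 replicates 1 and 2. The authors' size factors recovered in this way were 1.0184, 0.9844, 0.9916 and 1.0231 in the same order.

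Normalized counts, the recovered counts divided by the authors' size factors, are the unit of every level in the text, and means are given with the SD over 2 libraries. The deposited unit is a log scale and the recovered whole numbers can be rounded estimates, so limma was used and no negative binomial test was run. The planned test for normalized values applied: limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend, on log2(normalized count + 1), for genes with a mean of at least 1 normalized count, with Benjamini-Hochberg adjustment over all 13981 genes tested and a threshold of 0.05. The plan had allowed for counts or for normalized values per library and had not foreseen a variance-stabilized scale. A log2 fold change on this scale understates the change of low genes. The model held the group as its only term. Every adjusted p for a gene is two-sided and from this limma fit.

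A fold change given in words is the ratio of the mean normalized counts. Where both libraries of one group had a count of 0, the fold is a lower bound against a floor of 3 counts per library. Where a group held 1 to 3 counts, the ratio has a 95% exact counting interval. PCR copies are not independent molecules, so floors and intervals cover counting error only. A level under the floor was not detectable at this depth.

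Gene lists were tested with camera, the competitive test of limma, with a preset correlation of 0.01 between genes, two-sided, and adjusted over the 45 lists that had at least 5 tested members. A total of 49 lists had been written from textbook knowledge, none of them chosen on these samples. Each list was also tested with a correlation estimated from the data and with fry, a rotation test that asks whether the genes of a list move on balance one way. The count of members past the threshold is given over all genes tested and adjusted over the list alone.

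The groups, the tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Tert and Apc, which the labels give as altered. It named 12 genes with the largest rise and 12 with the largest fall, among genes past the threshold whose G2 libraries both lay on the same side of both G0 libraries and whose mean was at least 2, leaving out gene models without a proper name. It also named up to 4 members with the smallest p of each list described, and the sex-linked transcripts Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Xist had no row in the table, and some genes that the rule takes from the lists are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Gene positions are those of the RefSeq annotation of GRCm38.p6, the assembly also known as mm10, in which 16719 of the 16857 genes were found (99.2%), 16441 by symbol and 278 by a synonym. Transcript length and GC content came from GENCODE M21 and covered 98.0% of the genes.

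The tests were checked on simulated data made from the libraries' own means and depths, with 13839 genes tested and 200 of them changed. The fit recovered 90% of the 2-fold changes and 97% of the 4-fold changes of this comparison, with 1 false call among 188 and 0 calls in the wrong direction, and called 0 of 45 unchanged lists. The simulated genes shared one dispersion of 0.0108, so these shares are optimistic for genes that vary more between lines. They were also drawn independently of each other. The 0 of 45 therefore does not show how often the list test calls an unchanged list of correlated genes.

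Alternatives changed one choice at a time, except limma voom with library size scaling, which changed the model and the scaling together: the replicate number as a block, each library left out, the filter on low values, the pseudocount, quantile normalization, scaling by library size, limma voom on the recovered counts with library size scaling, and the threshold. Those added after the data were seen were limma voom with the authors' size factors, the deposited variance-stabilized values themselves, the comparison without X and Y genes, and the removal of length and GC trends from each library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the inversion, the tables and the plots.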

Results

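Gene expression was measured by bulk RNA sequencing in 4 mouse adenoma colonoid lines, of which 2 were labelled G0 and 2 G2. The lines are numbered 75 and 179 in G0 and 157 and 236 in G2. The G0 lines were labelled heterozygous and the G2 lines homozygous for an allele called LSL-mTERT of Tert, the catalytic subunit of telomerase, and all 4 were labelled as Apc-null. The series text describes a comparison of colonoids with low and high chromosomal instability, and the labels used here do not say which of these names belongs to which generation. Recovered totals lay between 16545429 and 17901744 counts per library. Between 14119 and 14215 genes had a count in a library, and the 10 most abundant genes took 6.39% to 7.78% of the counts.

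The libraries of one group were distinct from each other. The next measure used genes above a minimum summed count in the pair, 11930 in G0 and 12056 in G2. Over these the G0 pair differed by a chi-square of 34.4 per gene and the G2 pair by 25.4, both far above the sampling noise of a library sequenced again. Across genes, which are not independent replicates, the correlation of log2 values was 0.982 for the G0 pair, 0.973 for the G2 pair and 0.892 to 0.905 between groups. The first principal component, which held 80.6% of the variance, separated G0 from G2. Each library is a separate line, but nothing in the labels says that each line came from a separate mouse, so the p-values measure the spread between these lines alone.

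The first comparison concerns the altered genes themselves. Tert, on chromosome 13 from 73626911 to 73649843, stood at 95.4 ± 3.0 normalized counts in G0 and 0.5 ± 0.7 in G2 (SD, n = 2 each). It was 195-fold lower in G2, with a counting interval of 34.6 to 7750, and its log2 fold change was -6.10 with an SE of 0.54 (adjusted p = 0.00128). A single count of Tert was found in the G2 libraries together. Of the 26 telomerase, shelterin and telomere capping genes tested, Tert was the 1 gene that passed the threshold. This held both over all genes and adjusted over the list alone. The list as a whole did not pass the camera test (adjusted p = 0.162). Apc, the negative regulator of Wnt signalling, on chromosome 18 from 34220297 to 34322190, had 2346 ± 513 normalized counts in G0 and 2947 ± 557 in G2 and did not pass (adjusted p = 0.329). The labels name an Apc mutation, which a transcript level does not check.

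Sex-linked transcripts divided the libraries in the same way as the groups. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had a count of 0 in both G0 libraries. In G2 they stood at 524.2 ± 3.2, 424.4 ± 4.0, 385.2 ± 0.1 and 315.0 ± 26.6 normalized counts, at least 175-fold, 142-fold, 129-fold and 105-fold higher. The presence of Y transcripts therefore coincided with the group in 4 of 4 libraries, for every gene and list described here, and no fit can hold both terms.

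Between G2 and G0, 1467 of 13981 genes passed the limma test (10.5%), of which 829 were higher and 638 lower in G2. At least a 2-fold change was found for 619 of the higher and 401 of the lower genes, and at least a 16-fold change for 105 and 47. An unadjusted p under 0.05 was found for 3743 genes. Both G2 libraries lay on one side of both G0 libraries for 8079 genes (57.8%), where random labels give 33.3% on average. Genes move together and there are only 4 libraries, so the spread of that share is not known and no test is drawn from it. The count rested on having 2 libraries in each group. Without G0 replicate 1, G0 replicate 2, G2 replicate 1 or G2 replicate 2 the same limma test called 0, 2, 0 and 0 genes, with 3234, 2431, 2475 and 2484 genes at an unadjusted p under 0.05, and of the 131 genes past the threshold that the naming rule took, 0, 1, 0 and 0 were kept. The 1 kept was Hoxd13. Over 127 called genes with a count in both groups, those of the rule and others chosen after their values were seen, the ratio of the group means moved by over 1.5 times for 33 when 1 library was left out.

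**Figure D1:**
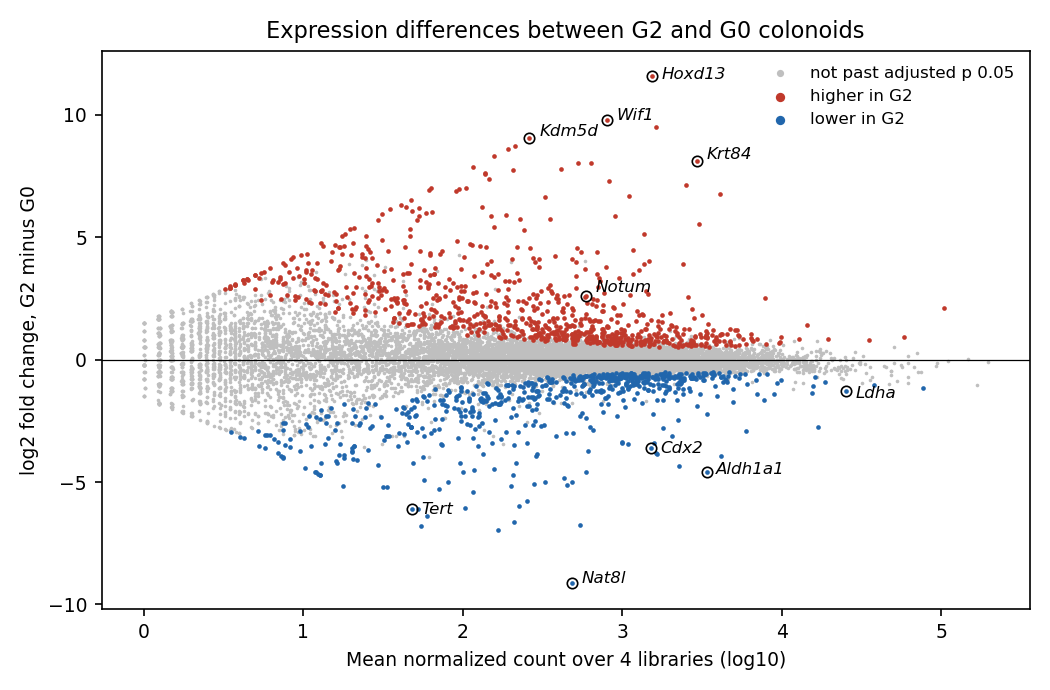
Log2 fold change of each tested gene, G2 minus G0 on the log2(normalized count + 1) scale, against its mean normalized count over the 4 libraries on a log10 scale. Red points are the 829 genes higher in G2, blue points the 638 lower, and gray points did not pass an adjusted p of 0.05. Hoxd13 has the highest and Nat8l the lowest fold change.

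The genes with the largest rise in G2 were of several kinds, with Hoxd13 first. Hoxd13, a transcription factor of the most posterior body axis on chromosome 2 from 74668225 to 74671603, had a count of 0 in both G0 libraries and 3072 ± 223 normalized counts in G2, at least 1030-fold higher (adjusted p = 1.64e-05). Wif1, a secreted protein that binds and inhibits Wnt ligands, on chromosome 10 from 121034004 to 121100642, rose from 1.0 ± 1.4 to 1610 ± 685, a ratio of 1640 with a counting interval of 454 to 13500. The endodermal transcription factors Sox17 and Gata5 rose from 3.0 ± 0.1 to 1059 ± 130 and from 5.1 ± 5.8 to 1266 ± 689 normalized counts. Smoc1, a secreted matricellular protein, was at 0 in G0 and at 232.8 ± 46.8 in G2, at least 77.9-fold higher. The keratins Krt34 and Krt84 rose from 2.5 ± 0.6 to 3264 ± 2919 and from 16.9 ± 3.8 to 5828 ± 4502, with a wide spread between the G2 lines. Gsdmc2, a gasdermin whose near-identical neighbours can share its reads, rose from 2.5 ± 0.8 to 819 ± 388 and is uncertain for that reason. The 4 Y-linked genes make up the rest of the 12 genes with the largest rise. Adjusted p for the genes of this paragraph ranged from 1.64e-05 for Hoxd13 to 0.00172 for Gata5.

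The genes with the largest fall were of mixed function. Nat8l, the enzyme that makes N-acetylaspartate, on chromosome 5 from 33995984 to 34005916, fell from 972.8 ± 102.4 to 1.0 ± 1.4 normalized counts, a ratio of 995 with a counting interval of 275 to 8220. B4galnt2, a glycosyltransferase of intestinal epithelium, fell from 330.3 ± 188.0 to 1.5 ± 0.7, a ratio of 221 with an interval of 75.2 to 1070. Dnajc6 (auxilin) fell from 109.8 ± 1.6 to 0 in both G2 libraries, at least 36.8-fold lower. The water channel Aqp5 fell 122-fold, from 1085 ± 309 to 8.9 ± 1.2, and the antimicrobial S100 gene S100a7a fell from 414.2 ± 26.2 to 3.5 ± 2.2. Tat, the tyrosine-degrading aminotransferase, and Cnfn, a cornified envelope protein, fell from 119.6 ± 19.1 and 104.6 ± 63.2 to 0.5 ± 0.7 each, ratios of 237 (interval 42.1 to 9400) and 214 (interval 38.0 to 8490). The adhesion receptor Adgrl3 fell from 205.8 ± 72.7 to 2.0, the interleukin 5 receptor gene Il5ra from 438.8 ± 44.5 to 8.5 ± 9.3, and Elmo1, a regulator of Rac, from 499.9 ± 7.1 to 9.0 ± 5.8. Pcdhga7 fell from 220.1 ± 47.0 to 12.6 ± 17.8 (adjusted p = 0.0460), but the gamma protocadherin transcripts share exons, so it is uncertain. Together with Tert these are the 12 genes with the largest fall, and adjusted p of those other than Pcdhga7 lay between 0.000165 for Aqp5 and 0.00427 for Il5ra.

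Of 25 Wnt/beta-catenin target genes, 7 rose and 2 fell over all genes, and 12 rose and 3 fell adjusted over the list alone. The target list had a median log2 fold change of 0.38 (camera adjusted p = 0.0194; adjusted p = 0.619 with an estimated correlation). Notum, a secreted enzyme that inactivates Wnt ligands, on chromosome 11 from 120653788 to 120661193, rose 6.02-fold from 169.7 ± 7.2 to 1021 ± 107 normalized counts (log2 fold change 2.58, SE 0.17, adjusted p = 0.000475). The Wnt inhibitor Dkk2 rose from 78.9 ± 3.3 to 603.7 ± 77.9, the transcription factor Prox1 from 119.0 ± 23.3 to 908.6 ± 27.0, and the feedback inhibitor Nkd1 from 256.0 ± 56.0 to 934.2 ± 45.2. Axin2, a feedback inhibitor and standard readout of the pathway, rose 1.76-fold from 4686 ± 104 to 8256 ± 1020 (adjusted p = 0.0171). Tcf7 and Tnfrsf19 fell, from 1228 ± 11.8 to 795.7 ± 5.7 and from 1393 ± 134 to 775.4 ± 176.6. The stem cell marker Lgr5 stood at 1208 ± 124 in G0 and 1173 ± 197 in G2 (adjusted p = 0.876); Lgr5, Tcf7 and Tnfrsf19 were chosen after their values were seen. Among 9 secreted Wnt antagonists, 3 rose, namely Wif1, Notum and Dkk2, and 0 fell; 5 rose adjusted over the list alone (median 1.23, camera adjusted p = 0.00952; adjusted p = 0.619 with an estimated correlation). The lists share 3 genes. The target list missed the threshold without G0 replicate 1 (adjusted p = 0.124) or G2 replicate 2 (0.0950), and the antagonists did so without the same libraries (0.171 and 0.182), and also without a filter on low values (0.0590). The antagonist median was 0.753 over 11 members without that filter and 2.58 over 7 members with a mean of at least 5.

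**Figure D2:**
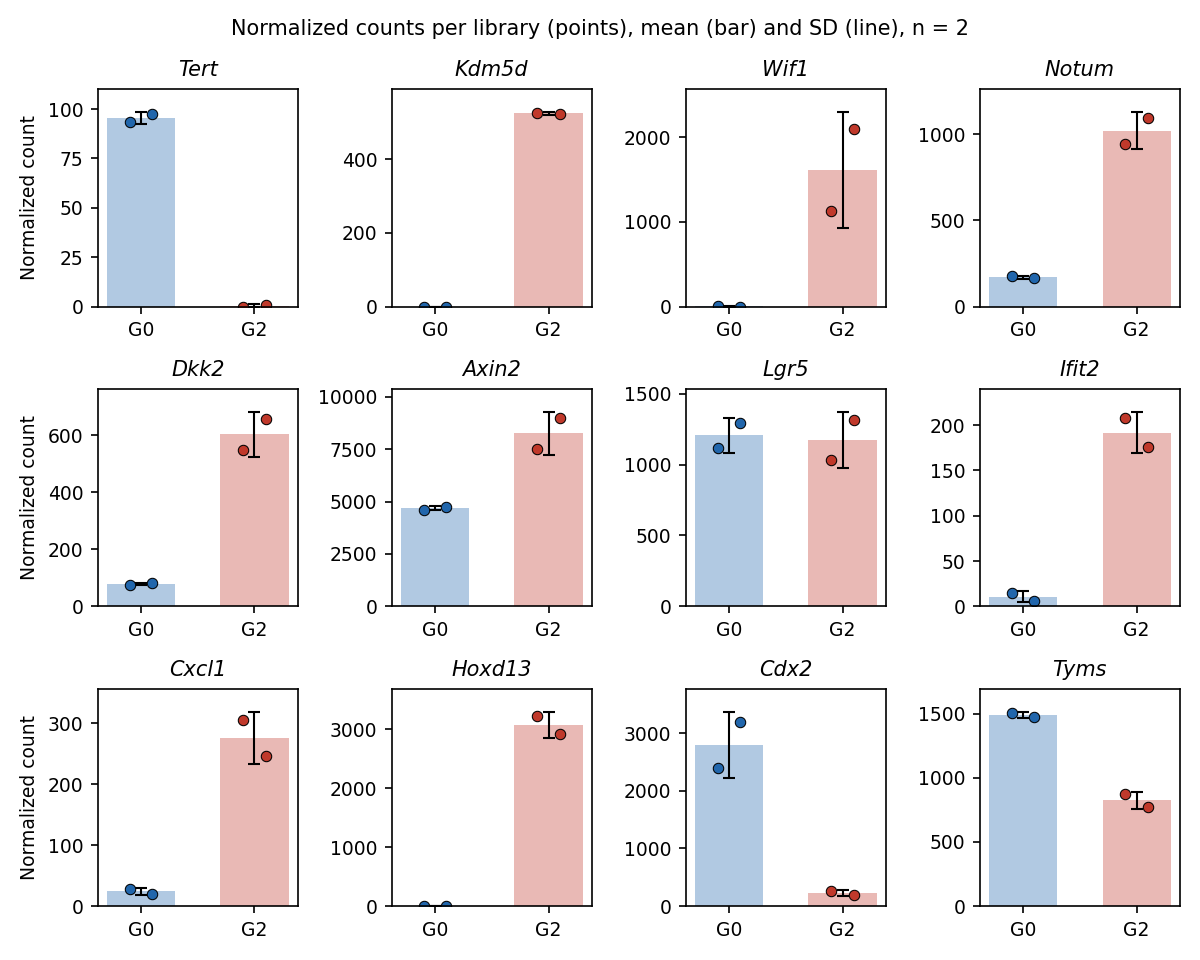
Normalized counts per library (points), group mean (bars) and SD (lines, n = 2) for 12 genes in G0 (blue) and G2 (red), each on its own linear axis from 0. Tert and Cdx2 are lower in G2, Lgr5 overlaps between groups at means of 1208 and 1173, and Kdm5d and Hoxd13 are at 0 in both G0 libraries.

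Of 36 interferon-stimulated genes, 12 rose and 0 fell over all genes, and 17 rose and 0 fell adjusted over the list alone. The list had a median log2 fold change of 1.04 (camera adjusted p = 5.73e-07; adjusted p = 0.530 with an estimated correlation). The antiviral genes Ifit2 and Oas2 rose from 10.4 ± 6.1 to 191.8 ± 22.5 and from 21.0 ± 3.3 to 185.6 ± 94.2 normalized counts (adjusted p = 0.00264 and 0.00692). Parp14 and Parp9, ADP-ribosyltransferases induced by interferon, rose 2.38-fold and 2.40-fold. Among 35 genes for cytokines, chemokines and other factors of the secretory phenotype, 12 rose and 3 fell over all genes, and 12 rose and 4 fell adjusted over the list alone. The median of this list was 0.997, or 0.867 with a gene at 0 in one group placed at its bound (camera adjusted p = 0.00149; adjusted p = 0.530 with an estimated correlation), and 0.495 with a pseudocount of 5. The chemokine genes Ccl20, Cxcl1 and Ccl7 rose from 7.0 ± 0.2 to 214.9 ± 39.8, from 24.4 ± 5.8 to 275.5 ± 42.6 and from 5.5 ± 0.8 to 143.5 ± 45.3. The cytokine gene Il18 rose 10.8-fold, from 87.1 ± 24.0 to 939.5 ± 277.6. Those that fell included Ccl9 and Igfbp7, which were chosen after their values were seen. Of 19 NF-kappaB response genes, which share 3 members with the cytokine list, 5 rose and 1 fell over all genes, and 8 rose and 1 fell adjusted over the list alone. The NF-kappaB median was 0.34 (camera adjusted p = 0.00249; adjusted p = 0.619 with an estimated correlation), and the list missed the threshold without G2 replicate 2 (adjusted p = 0.0950). Its median was 0.225 without G0 replicate 1 and 0.568 without G2 replicate 1. Besides Ccl20 and Cxcl1 the genes that passed were Nfkbiz and Nfkbie, regulators of the pathway, at 2.90-fold and 2.39-fold, then Cxcl2, which rose, and Tnfaip2, which fell, both chosen after their values were seen. Macrophage markers stood beside these lists with a median of 0.96 and 6 of 7 members above 0, and did not pass as a list (camera unadjusted p = 0.0272, adjusted p = 0.0721). Of them Cd14 rose from 1110 ± 169 to 2152 ± 65 normalized counts and Csf1r from 0 in both G0 libraries to 10.5 ± 8.0 (adjusted p = 0.0107 and 0.0431), and Laptm5 stood at 1.0 ± 0.0 in G0 and 15.3 ± 11.6 in G2 (adjusted p = 0.0550). The 11 cytosolic DNA sensing genes tested included 0 that passed the limma test over all genes or adjusted over the list alone. Ifi204 had the smallest p among them, at 7.0 ± 1.6 and 24.3 ± 1.2 normalized counts (unadjusted p = 0.00824, adjusted p = 0.0644).

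Of 26 proliferation genes, 14 fell and 0 rose over all genes, and 21 fell and 0 rose adjusted over the list alone. The proliferation list had a median of -0.60 (camera adjusted p = 5.70e-11; adjusted p = 0.530 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell from 3698 ± 95 to 2136 ± 95 normalized counts (log2 fold change -0.79, SE 0.13, adjusted p = 0.0110). Cdt1, which loads that helicase, fell 1.91-fold, and the nucleotide synthesis genes Tyms and Rrm2 fell 1.81-fold and 1.82-fold. The division marker Mki67, chosen after its values were seen, stood at 7650 ± 37 in G0 and 7027 ± 1942 in G2 (adjusted p = 0.669). A list of 47 genes of published chromosomal instability expression signatures, which shares 7 members with it, had 13 that fell and 0 that rose over all genes, and 31 and 0 adjusted over the list alone. Its median was -0.52 (camera adjusted p = 5.70e-11; adjusted p = 0.530 with an estimated correlation). Cep55, needed for the last step of cytokinesis, fell 2.51-fold from 1388 ± 85 to 553.9 ± 3.2, the cyclin gene Ccnb2 fell 1.76-fold, and Espl1, which encodes separase, fell 1.62-fold. Members of that list are mostly mitotic and replication genes. Of 34 DNA damage and double-strand break repair genes, 2 fell over all genes, Rpa2 and Fanca, at 1.83-fold and 1.57-fold, and 0 passed the limma test adjusted over the list alone. The repair list had a median of -0.26 (camera adjusted p = 0.0211; adjusted p = 0.768 with an estimated correlation), and it missed the threshold without G0 replicate 1 (adjusted p = 0.171) or G2 replicate 2 (0.133), where its median was -0.143.

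Of 24 hypoxia and glycolysis genes, 6 fell and 0 rose over all genes, and 8 and 0 adjusted over the list alone. Its median was -0.90 (camera adjusted p = 9.87e-07; adjusted p = 0.774 with an estimated correlation), and -0.52 without G0 replicate 2. Car9, a carbonic anhydrase induced by hypoxia, stood at 3086 ± 1480 and 517.9 ± 430.1 normalized counts (adjusted p = 0.0320), and P4ha1, Hk2 and Pfkp fell 2.13-fold, 1.63-fold and 2.57-fold. Of 22 antioxidant genes regulated by NRF2, 10 fell and 2 rose over all genes, and 15 fell and 2 rose adjusted over the list alone. The median of these genes was -0.86 (camera adjusted p = 6.60e-06; adjusted p = 0.530 with an estimated correlation). The retinal dehydrogenase gene Aldh1a1 fell from 6476 ± 391.8 to 300.4 ± 187.0 (adjusted p = 0.00110) and the malic enzyme gene Me1 fell 2.81-fold, while the cystine transporter gene Slc7a11 rose from 56.0 ± 33.3 to 916.2 ± 303.1 and Gsta4 rose 2.35-fold. Of 23 cholesterol biosynthesis genes, 5 fell and 0 rose over all genes, and 6 and 0 adjusted over the list alone. The cholesterol median was -0.20 (camera adjusted p = 0.00149; adjusted p = 0.619 with an estimated correlation), and -0.32 without G2 replicate 1. The genes that fell included Acat2, Insig1 and, chosen after its values were seen, Stard4. Acat2, an acetyl-CoA acetyltransferase, fell 1.63-fold, from 2540 ± 255 to 1562 ± 172 normalized counts, and Insig1, a sterol-regulated inhibitor of the pathway, fell 1.49-fold. Of 21 genes of the unfolded protein and integrated stress responses, 3 fell and 1 rose over all genes, and 7 fell and 3 rose adjusted over the list alone. The stress list had a median of -0.25 (camera adjusted p = 0.0224; adjusted p = 0.742 with an estimated correlation), and it missed the threshold without G0 replicate 2 (adjusted p = 0.0705) or G2 replicate 2 (0.121; median -0.161), and after the length and GC correction (0.0689). The 3 that fell encode enzymes of asparagine and serine synthesis: Asns fell 2.22-fold, Psat1 from 3072 ± 111 to 1535 ± 72 normalized counts and Phgdh 1.77-fold.

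The 47 cytosolic ribosomal protein genes and 29 nuclear-encoded oxidative phosphorylation genes had 0 single genes past the limma threshold over all genes or adjusted over either list alone. The ribosomal median was -0.34, with 46 genes below 0 (camera adjusted p = 3.67e-05; adjusted p = 0.893 with an estimated correlation), and Rpl8, with the smallest p, had 18500 ± 3750 normalized counts in G0 and 13250 ± 2081 in G2. The ribosomal call was lost without G0 replicate 2 (adjusted p = 0.117, median -0.096) or G2 replicate 1 (0.0809, median -0.187), and the median was -0.56 without G0 replicate 1, -0.195 after quantile normalization and -0.183 after the length and GC correction. The oxidative phosphorylation median was -0.29, with 26 genes below 0 (camera adjusted p = 0.000366; adjusted p = 0.825 with an estimated correlation), and Sdha stood at 2855 ± 206 and 2054 ± 60. That median was -0.178 without G0 replicate 2, -0.193 without G2 replicate 1 and -0.176 after the length and GC correction.

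Of 13 distal colon genes, 7 rose and 2 fell over all genes, and 8 rose and 2 fell adjusted over the list alone. The median of the list was 1.74, or 1.16 with genes at 0 in one group placed at their bounds (camera adjusted p = 0.00877; adjusted p = 0.742 with an estimated correlation), and it missed the threshold without G0 replicate 1 (adjusted p = 0.118). Without G2 replicate 1 the median was 0.983, and with a pseudocount of 5 it was 1.14. Besides Hoxd13, Hoxd9 was at 0 in both G0 libraries and at 88.6 ± 70.0 normalized counts in G2, at least 29.7-fold higher, and Hoxb13 rose from 358.2 ± 181.6 to 1652 ± 390 (adjusted p = 0.00950). The 2 that fell were Ly6g, from 11670 ± 681 to 3823 ± 1081, and Hoxa11, chosen after its values were seen, from 766.1 ± 19.8 to 385.3 ± 82.7. Of 11 caecal and proximal colon genes, Cd177 rose from 5.0 ± 1.3 to 89.6 ± 24.0 and Fut2 fell 1.69-fold over all genes, 3 rose and 3 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.926). The 9 small intestinal genes did not pass either (adjusted p = 0.956), with Slc10a2 higher at 2.0 ± 1.4 and 21.5 ± 13.8 and Ada 2.53-fold lower.

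**Figure D3:**
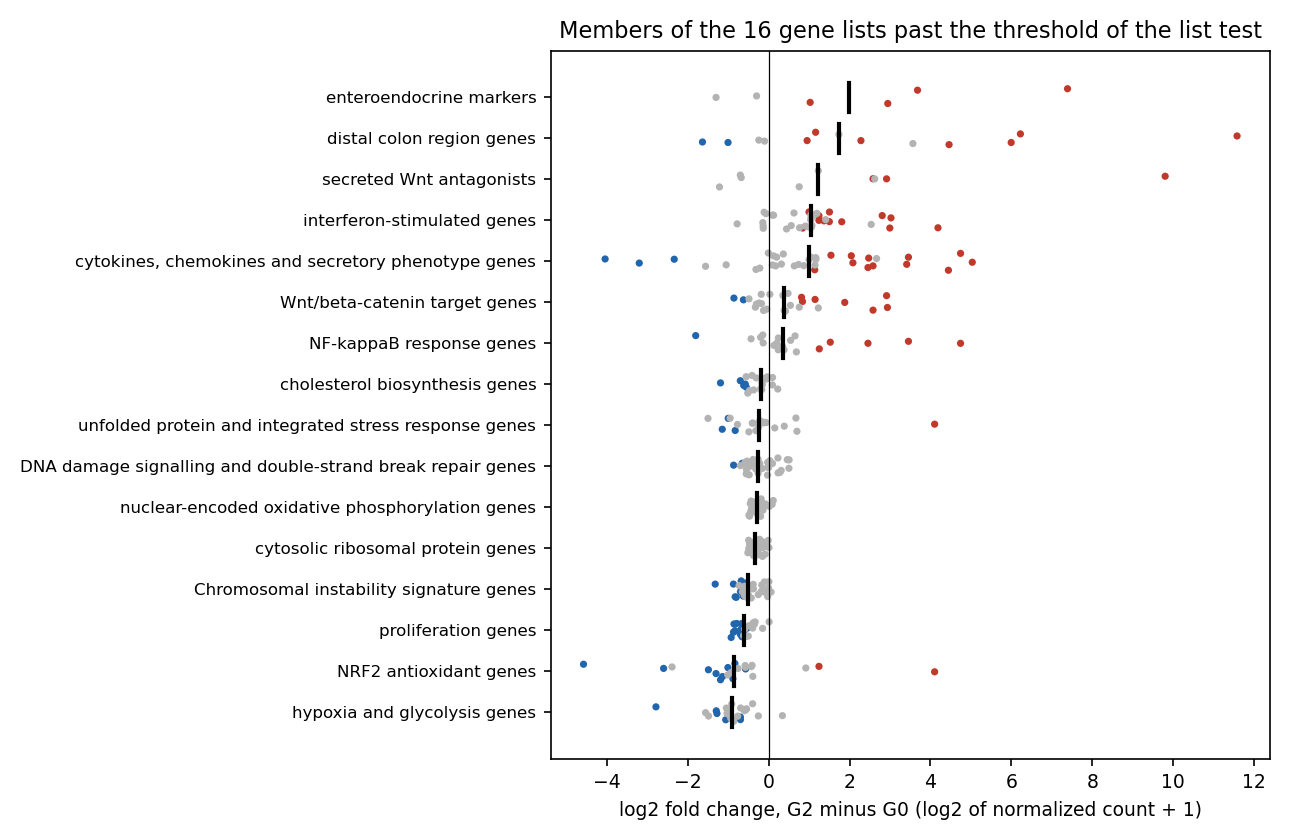
Log2 fold change of each tested member (points) of the 16 gene lists past the threshold of the camera test with its preset correlation, with the list median (black bar). Red members were higher and blue members lower in G2 at an adjusted p of 0.05 over all genes, and gray members did not pass. The 6 enteroendocrine markers tested have a median of 1.98, which was 0.492 over 13 members without a filter on low values, and the hypoxia and glycolysis genes one of -0.90.

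Of 21 enteroendocrine markers fixed, 19 had a row and 6 passed the filter on low values and were tested. That filter took the mean over all 4 libraries, so a marker at 0 in G0, such as Insm1, could pass it through G2 alone. Of the 6 tested, 4 rose over all genes and adjusted over the list alone, and 0 fell. The median of the list was 1.98, or 1.118 with genes at 0 placed at their bounds (camera adjusted p = 0.0252; adjusted p = 0.619 with an estimated correlation), and it missed the threshold without G0 replicate 1 (adjusted p = 0.118) or G2 replicate 2 (0.111). The median depended on which members were tested and on the pseudocount: it was 0.492 over 13 members without a filter on low values, 1.15 without G0 replicate 1, 3.29 with a pseudocount of 0.1 and 1.11 with one of 5. With a mean of at least 5 too few members were left for a list test. The 4 were the transcription factors Isl1, from 1.0 ± 1.4 to 290.0 ± 56.2, and Insm1, from 0 to 6.9 ± 2.7, with Nts, from 1.0 ± 1.4 to 21.8 ± 7.9, and Cpe, 2.05-fold higher. The enteroendocrine list also missed the threshold without a filter on low values (0.0760), with a pseudocount of 0.1 (0.0532) and with limma voom and library size scaling (0.0531). Of 15 crypt base stem cell markers, 3 rose and 3 fell over all genes (list adjusted p = 0.555), among them Hopx, 3.05-fold higher, and Lrig1, 2.08-fold lower. Of 21 colonocyte markers 4 rose and 3 fell (adjusted p = 0.950): Slc9a3, a sodium exchanger, rose from 32.4 ± 5.6 to 571.4 ± 36.5, and the brush border gene Vil1 fell from 5558 ± 1166 to 1259 ± 667. Of 12 goblet markers 1 rose and 2 fell (adjusted p = 0.791), and of 10 tuft cell markers 2 rose and 1 fell (adjusted p = 0.442), the last being Alox5, from 297.9 ± 28.3 to 14.5 ± 10.9, a ratio of 43.8 without G2 replicate 1. Among 18 gastric, pancreatobiliary and stratified epithelial genes, 6 rose and 2 fell (adjusted p = 0.0845), including Krt14 and Krt6a, 3.06-fold and 2.97-fold higher, and Sox2, at 0 in G0 and 35 ± 19.0 in G2. Adjusted over the list alone, 4 stem cell, 5 colonocyte, 2 goblet, 3 tuft and 9 gastric or stratified genes rose, and 3, 6, 5, 1 and 3 fell. Fibroblast, smooth muscle, endothelial and macrophage lists did not pass (adjusted p = 0.657, 0.678, 0.915 and 0.0721). Single markers in them passed nonetheless, beside the changes in the epithelial lists. Of 9 smooth muscle markers Acta2, a contractile actin, rose from 6.0 ± 2.7 to 309.3 ± 176.4, and 0 fell. Of 9 endothelial markers 2 rose and 0 fell, Tek from 3.5 ± 0.8 to 46.2 ± 1.7 and Vwf from 20.5 ± 4.0 to 59.0 ± 10.6 (adjusted p = 0.00587 and 0.0496). Of 7 macrophage markers 2 rose, Cd14 and Csf1r, and 0 fell. Of 5 fibroblast markers Col3a1 rose from 0 in both G0 libraries to 7.0 ± 0.2 (adjusted p = 0.0404) and Fbln1 fell 3.01-fold, while Col1a1 stood at 4.5 ± 0.6 in G0 and 1.5 ± 0.7 in G2. Adjusted over the list alone, 1 smooth muscle, 2 endothelial, 3 macrophage and 1 fibroblast markers rose, and 0, 2, 0 and 1 fell. Only 2 T cell and 2 B cell markers were tested, too few for a list test.

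The lists of p53 targets, cell competition, TGF-beta family, fetal-like and YAP/TAZ genes did not pass the camera test. Of 36 p53 target genes, 3 rose over all genes (list adjusted p = 0.859), namely the pro-apoptotic gene Pmaip1, from 341.5 ± 129.5 to 1423 ± 10, with Plk2, from 1663 ± 39 to 2503 ± 85, and Trp53inp1, from 981.3 ± 520.1 to 2387 ± 373, a ratio of 3.89 without G0 replicate 1; 2 rose adjusted over the list alone. Of 19 genes studied in cell competition, Notum alone passed, over all genes and adjusted over the list alone (list adjusted p = 0.803). Of 26 TGF-beta, activin and BMP ligands and inhibitors, 1 rose and 3 fell (list adjusted p = 0.704), with Bmp8b 10.1-fold lower, from 2864 ± 32 to 283.7 ± 115.1, Fst 6.54-fold and Tgfb3 2.30-fold lower, and Bmp7 2.97-fold higher. Of 27 fetal-like and regenerative genes, 5 rose and 2 fell (adjusted p = 0.703), with Emp1 4.57-fold lower and Ly6d 7.27-fold higher, and of 21 YAP/TAZ targets 3 rose and 2 fell (adjusted p = 0.779), with Ankrd1 6.50-fold lower. Adjusted over the list alone, 1 TGF-beta family, 7 fetal-like and 5 YAP/TAZ genes rose, and 4, 5 and 3 fell. The median and the camera test differed in sign for the lists of MHC class II, goblet, colonocyte, small intestinal, proximal colon, cytosolic DNA sensing, Notch, TGF-beta response, apoptosis and epithelial-mesenchymal transition genes, none of which passed.

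Every list not among the 16 had a camera adjusted p between 0.0721 and 0.956 in the reported fit. The list tests depended on whether the correlation between genes was preset or estimated. The estimate was 0.955 for the ribosomal protein list. It was -0.00046 for the chromosomal instability signature and -0.024 for the Wnt targets, below the preset 0.01. A higher correlation was therefore not what weakened the test of the signature and Wnt target lists. With an estimated correlation camera takes its degrees of freedom from the 4 libraries, and with a preset one from the genes. The unadjusted camera p of the signature went from 1.82e-12 to 0.0135 between these settings. A call lost with an estimated correlation is therefore not by itself evidence that the genes of a list are correlated. With the preset correlation 16 of 45 lists passed, with an estimated correlation 0 passed after adjustment and 3 had an unadjusted p under 0.05, namely the chromosomal instability signature (0.0135), proliferation (0.0454) and interferon (0.0401) lists. The rotation test fry kept 11 of the 16 and lost DNA repair, hypoxia and glycolysis, oxidative phosphorylation, ribosomal protein and stress response genes. It called 14 lists in all, and the 3 that camera had not called were telomere maintenance, tuft cell and cell competition genes (fry adjusted p = 0.0128, 0.0372 and 0.0425). Tert, which the labels give as altered, was the only telomere maintenance gene past the limma threshold, and Notum the only cell competition gene. Fry was not run without them, so these calls do not show that the other members moved.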

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

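Limma voom with the authors' size factors, the deposited scale, the removal of X and Y genes and the length and GC correction were chosen after the data were seen. The 1467 calls became 3503 (1859 higher, 1644 lower) with the replicate number as a block, but equal numbers are different lines, and no label gives what they share. Equal numbers deviated together to some extent (correlation 0.20), and the second principal component separated replicate 1 from replicate 2 in both groups, a hint from the data that 2 pairs cannot settle. Replicate 1 minus replicate 2 also ran with GC content in the same direction in both groups (Spearman rho -0.55 in G0 and -0.21 in G2). The correlation was not computed after the length and GC correction. Leaving out each library gave 0 to 2 calls (0 to 2 higher, 0 lower) by limma, with 2431 to 3234 genes at an unadjusted p under 0.05. These fits have fewer samples, and the lone library is assumed to vary like the pair of the other group; 0 of the 1467 calls changed sign. An adjusted p under 0.1 gave 2426 calls (1324 higher, 1102 lower), one under 0.01 gave 495 (309 and 186), and asking for at least a 2-fold change left 401 lower. After the length and GC correction 1005 genes were lower, and the cause was not tested. Across the remaining settings the count ran from 1065 without a filter on low values to 2125 after that correction, and 0 calls changed sign. Calls that were higher made up 62.8% with library size scaling, 62.4% with limma voom at that scaling, 55.4% with limma voom at the authors' size factors and 56.5% in the reported fit. Of the 131 genes past the threshold that the naming rule took, 111 to 131 kept it outside the left-out libraries where tested. With a correlation estimated per list 0 lists passed after adjustment and 3 before it. Other settings kept 10 to 16 of the 16 lists, with none turned. Some settings also called lists outside the 16. Without a filter on low values 15 lists passed the camera test, of which 14 were among the 16. After the length and GC correction 16 passed, of which 15 were among them. The TMM scaling and the edgeR count test were not run, because they were planned for deposited counts and the deposited unit is a log scale. A DESeq2 count test was not run either. The reported fit already used the authors' size factors, so median-of-ratios scaling was not run again. Depth limits genes under 3 counts per library.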

Other observations

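The families of keratin, Hox, gasdermin C and small proline-rich genes, Cdx2, Evx2, the test of distal origin, the test of autosomes shared by both G2 lines and the test of spread within groups were chosen after the data were seen. Of 33 keratin genes tested, 13 were higher and 3 lower in G2; no enrichment is claimed, since the family was picked from genes already seen to rise. Krt36, a hair-type keratin, rose from 123.0 ± 11.4 to 5890 ± 1181 normalized counts (limma adjusted p = 5.40e-05), Krt90 from 190.5 ± 65.3 to 2361 ± 371, and Krt13 from 257.5 ± 74.0 to 4539 ± 3542. In the other direction Krt4, a keratin of stratified epithelia, stood at 28650 ± 6514 in G0 and 5003 ± 3777 in G2 (adjusted p = 0.0180). Of 4 gasdermin C genes tested, 3 were higher and 0 lower. Gsdmc2, Gsdmc3 and Gsdmc4 can share reads, which was not measured, so they are uncertain as separate genes. Of 7 small proline-rich genes 1, Sprr2b, was higher. No call in these families changed sign under any setting.

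Of 25 Hox genes, 6 were higher and 3 lower in G2. On chromosome 2, Evx2 (74652989 to 74661520), the direct neighbour of Hoxd13, was at 0 in G0 and at 126.7 ± 7.7 normalized counts in G2, at least 42.4-fold higher, and Hoxd11 was at 0 and 117.7 ± 141.6. Hoxa13 rose 2.25-fold, from 142.0 ± 17.5 to 319.8 ± 55.5 (adjusted p = 0.0233), while Hoxa7, Hoxa11 and Hoxb9 fell. Cdx2, the homeobox regulator of intestinal identity on chromosome 5 from 147300900 to 147307249, fell 12.2-fold, from 2797 ± 568 to 228.5 ± 59.1 (log2 fold change -3.62, SE 0.23, adjusted p = 0.000430).

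The Hox and Cdx2 pattern was weighed against other cells and against origin. Stromal cells, which express posterior Hox genes, would bring collagen transcripts, but the highest mean of Col1a1, Col1a2 and Col3a1 in G2 was 7.0 normalized counts against 3072 for Hoxd13, which argues against them as the source of Hoxd13. The rises of Acta2, Tek, Vwf, Cd14 and Csf1r were not explained by this test. A candidate explanation is that the G2 lines came from a more distal part of the colon: Hoxa13, Hoxb13 and Hoxd13 all rose, the smallest by 1.16 log2 units. That test used genes already seen and did not cover the fall of Cdx2, and no label gives the site. The Tert genotype, generation and Y-linked reads all divide the 4 libraries alike.

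Y-linked reads in both G2 libraries and in neither G0 library could come from G0 lines that carry 2 X chromosomes and G2 lines that carry 1, or from loss of the Y in the G0 lines, and these cannot be told apart here. The X genes that escape inactivation and have a Y partner had a median log2 fold change of -0.38, with 3 of 4 below 0. This met the bound set for 2 X chromosomes in G0 before the values were seen, a median of -0.3 or lower. Kdm5c at -0.70 and Eif2s3x at -0.74 passed (adjusted p = 0.0206 and 0.0341), while Ddx3x at -0.05 and Kdm6a at 0.49 did not (adjusted p = 0.894 and 0.122). The question was left open all the same, since Kdm6a stood higher in G2 by more than its SE and Xist had no row; that reason was found after the values were seen. X and Y genes themselves made up few of the calls, with 52 of 436 genes tested on the X and 4 of 5 on the Y. The count of calls with X and Y genes was 1.013 times that without them. So few genes could not have lowered the count by much, so that ratio decides nothing. Of 21 chromosomes the Y alone held more calls than its share (Fisher's exact test, adjusted p = 0.0114). That result follows from the Y-linked reads already described and adds no evidence of its own. Effects of sex on the other 1411 calls cannot be told apart from those of the group, because no fit can hold both.

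The proliferation, chromosomal instability signature and glycolysis lists, with medians below 0 and calls that were lost with an estimated correlation (adjusted p = 0.530, 0.530 and 0.774), were weighed against scaling and sequence bias. Quantile normalization left the proliferation median at -0.62, beside -0.60 as reported. The median log2 fold change over all genes was already 0.012 in the reported fit, and it was -0.023 after quantile normalization. Rescaling therefore had little room to move the list, and this test decides little about scaling. The length and GC correction left the proliferation median at -0.58, which argues against sequence bias as the whole cause for that list. The correction had something to remove: log2 differences between the G0 libraries ran with GC content at a Spearman rho of -0.55 across 11410 genes, against -0.21 for the G2 pair and -0.16 for G2 minus G0. Culture density or time since passage could also lower glycolysis and division genes, and with the hypoxia and glycolysis median at -0.90, or -0.52 without G0 replicate 2, and no label on passage or density they cannot be told apart from the group. A difference tied to Tert genotype or generation stays open as well.

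A further hypothesis was that a G2 line might have gained or lost whole autosomes that the other G2 line kept. The largest median log2 difference of an autosome between the G2 libraries was 0.044, on chromosome 16, where one extra copy in all cells would give 0.58, and the G0 pair reached 0.139. Gains or losses shared by both G2 lines in all cells were argued against by the largest G2 minus G0 difference of an autosome, 0.065 in size on chromosome 19. Over windows of 50 genes on the autosomes the largest median difference was 0.187 in the G2 pair, 0.334 in the G0 pair and 0.288 between groups, and gains in part of the cells or of shorter segments stay open. Whether the G2 lines were more spread than the G0 lines cannot be told apart from single lines that differ, with 1 pair in each group and measures that disagree. The median absolute log2 difference was 0.178 in the G2 pair and 0.231 in the G0 pair, a ratio of 0.77, but after the length and GC correction it was 0.163 and 0.162. More genes differed by over 1 log2 unit in the G2 pair (441) than in the G0 pair (227), and after the correction 416 and 164 did.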
